A study of Mus musculus with 4 samples.

How the data were processed

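Chromatin accessibility was profiled in mouse brain parenchymal macrophages isolated by fluorescence-activated sorting, with the Omni-ATAC variant of ATAC-seq, per the labels' protocols. In this assay the Tn5 transposase inserts sequencing adapters into open chromatin, so that fragment pile-ups mark accessible regions. The 4 libraries carried the labels MDM1, MDM2, YSM1 and YSM2, which gave 2 groups of 2. MDM was read as the monocyte-derived macrophages of the series title, and the labels do not spell out YSM. All 4 libraries had the genotype label Ms4a3-Ai9. Ms4a3 is a gene of granulocyte and monocyte progenitors and Ai9 is a Cre-dependent red fluorescent reporter allele. All 4 also had the treatment label DR-3x, whose meaning the labels do not give. Nothing in the labels says whether the 2 libraries of a group came from separate animals.

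The authors used Trimmomatic 0.39, Bowtie2 2.2.5, Picard and HOMER with the mm10 build, per the submitters' processing notes, which give the tools without their settings. The authors merged the peaks of the 4 libraries with HOMER mergePeaks, per the file headers. Peaks had thus been called per library before merging. The settings of the peak caller and any shift of reads for the Tn5 offset are not given in the sources used here. The deposited merged list held 74695 intervals. The authors' differential peaks came as 2 lists, which their names tie to DESeq2 and to the MDM or the YSM group, with 108 and 1104 intervals. The deposited lists gave no fold change, score or p-value that could be read as such, and the thresholds behind them are not given in the sources used here. A listed peak was taken, from the name of its list, as more accessible in that group than in the other. These intervals carried no value per library, so the spread between replicates could not be measured, and the depth of each library was not analysed here.

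Each merged peak carried the number of library-level peaks (subpeaks) that had been combined into it. This reading was checked on the coordinates. All 15127 intervals with a single subpeak were 201 bp wide, and 0 intervals were wider than their number of subpeaks times 201 bp. With at most 3 subpeaks, at least 1 of the 4 libraries had no called peak in the interval. With 4 or more, each library can have had a call, but a library can also have given several. Coordinates were written 1-based.

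Gene positions came from the RefSeq gene table of assembly GRCm38.p6, whose primary chromosomes are those of mm10. As a check on the match, 21.5% of the merged peaks lay within 1000 bp of the start or end of a protein-coding gene, and 4.36% did after every peak was moved by 1000000 bp. The table gave gene intervals without strand, exons or untranslated regions. The transcription start sites, promoters, exons and introns named in the design were therefore replaced. A peak was assigned to the nearest of 21887 protein-coding genes, at 0 bp if its centre lay inside one, up to 100000 bp. Its place was called gene edge if its centre lay within 1000 bp of either end of a gene, otherwise inside a gene or outside genes. Exonic and intronic positions could not be told apart in this way. Distances from a peak to its assigned gene ran from the peak's centre. A peak placed outside a gene by its centre could therefore still overlap the gene. Base composition and transcription factor motifs were part of the design and were not analysed here, since no genome sequence was used.

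The background of each test was the 73483 merged peaks in neither list. Shares were compared with two-sided Fisher's exact tests, with odds ratios and 95% intervals from the logarithm of the odds ratio. Benjamini-Hochberg adjustment ran over the 48 gene list tests, the 9 tests of gene position and the 40 chromosome tests, with a threshold of 0.05 on adjusted p. The chromosome and gene position tests left out unplaced sequences. Median widths were compared with two-sided permutation tests of 100000 resamples. Clustering was tested one-sided against 10000 random draws of merged peaks from the same chromosomes. For each gene with at least 2 merged peaks, a one-sided hypergeometric test asked whether it held more listed peaks than a random draw would give. That test, the comparison of subpeak numbers and the region around Sall1 were chosen after seeing the data. Peaks are not replicates and neighbouring peaks are not independent, so all p-values describe these lists and say nothing of the spread between animals.

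The 16 gene lists, with 476 genes in all, were fixed before the data were examined. They covered microglial identity, monocytes and monocyte-derived macrophages, border-associated macrophages, antigen presentation, interferon response, disease-associated microglia, inflammation, lipid and cholesterol handling, TGF-beta and SMAD signalling, macrophage transcription factors, Hox and progenitor genes, phagocytosis and complement, neutrophils, lymphocytes, neuron, glia and vessel markers, and the cell cycle. In the gene table, 473 of the 476 matched a protein-coding symbol. The rule for named genes, also fixed then, took for each differential list the 12 genes with most assigned peaks, ties by the smallest distance, and the genes of the fixed lists with at least 1 assigned peak. Distances in this rule ran to the gene interval and then to the nearer gene end in place of the transcription start site. Alternatives changed the gene assignment, the gene set, the background, the treatment of neighbouring peaks, the chromosomes and the number of subpeaks.

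The tests were checked on simulated lists of 300 peaks drawn from the 74695 merged peaks. With no effect, 14 of 200 lists were called at p below 0.05, and with planted odds of 4, 196 of 200 were called, at a median odds ratio of 4.05. Where list membership and the gene list both depended on a simulated confounder alone, the unstratified Fisher test used for the main results called 33 of 200, and the test stratified on that confounder 7 of 200. The main tests therefore do not remove the effect of a peak property that goes with both. The simulated lists were drawn peak by peak, without the clustering of the real lists along the genome. Their error rates therefore need not hold for real lists, where several peaks share a gene. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.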

Results

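Accessible chromatin was mapped in sorted mouse brain parenchymal macrophages of 2 groups, MDM and YSM, with 2 libraries each. The peaks of the 4 libraries merged into 74695 intervals. The series title asks how monocyte-derived macrophages that engraft the brain differ by where they come from. The comparison made by these lists was MDM against YSM. No values per library entered the comparisons, so no replicate error is given.

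The YSM list held 1104 peaks and the MDM list 108, which was 1.48% and 0.145% of the merged peaks. YSM-listed peaks lay at 654 genes, and Magi1, Klf12, Ptprm, Adamts16, Sall1 and Slc1a3 each held 7 or more of them. MDM-listed peaks lay at 82 genes, of which Kcng2, Irs2, Ubl3, Sema6d and Armc2 held 2 each and the others 1. The YSM list was 10.2 times as long (95% exact interval 8.38 to 12.6, two-sided exact binomial p = 1.82e-208). That test set lists of equal length as its null and took each peak as independent. Its interval and p-value therefore do not cover the spread between libraries. Among listed peaks with at least 4 subpeaks, a restriction chosen after seeing the data, the ratio fell to 3.29 (2.61 to 4.19), with 313 YSM-listed and 95 MDM-listed peaks. All 1212 listed peaks matched a merged peak exactly, and 0 merged peaks were in both lists.

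Both differential sets lay less often at gene ends than the other merged peaks. Of the YSM-listed peaks, 11.2% (123 of 1102) were at a gene edge, against 21.7% of the peaks in neither list (odds ratio 0.45, 95% interval 0.38 to 0.55, adjusted p = 1.38e-18). Of the MDM-listed peaks, 4.63% (5 of 108) were (odds ratio 0.18, 0.071 to 0.43, adjusted p = 4.88e-06, and 0.37, adjusted p = 5.85e-04, with genes of every annotated kind). YSM-listed peaks were more often inside genes, at 54.9% against 45.6% (odds ratio 1.45, 1.29 to 1.64, adjusted p = 4.54e-09). MDM-listed peaks were more often outside genes, at 53.7% against 32.7% (odds ratio 2.39, 1.64 to 3.49, adjusted p = 1.69e-05). The MDM and YSM lists themselves differed in the share outside genes (odds ratio 2.26, 1.52 to 3.36, adjusted p = 1.50e-04). Their differences at gene edges (odds ratio 0.39, adjusted p = 0.0421) and inside genes (0.59, adjusted p = 0.0168) did not pass the threshold when genes of every annotated kind were used (adjusted p = 0.373 and 0.0996), and the first also missed it with peaks of at least 2 subpeaks (adjusted p = 0.0781).

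The microglial identity list was over-represented among YSM-listed peaks, mostly through Sall1, Nav3 and Sall3. The list, made of genes that mark brain-resident microglia, took 21 of 1104 YSM-listed peaks (1.90%) against 0.393% of the peaks in neither list, and 0 of 108 MDM-listed peaks. The YSM odds ratio was 4.91 (95% interval 3.14 to 7.68, Fisher's exact test, adjusted p = 5.47e-07). The peaks belonged to 6 of the 33 list genes with merged peaks. Sall1, a zinc-finger transcription factor that maintains microglial identity, held 7, Nav3 held 6, and Sall3, a paralogue of Sall1, held 5. Sparc, Ecscr and Adgrg1 held 1 each. The other 27 list genes with merged peaks held no listed peak. The list was not tested without Sall1, Nav3 and Sall3 together, so an excess beyond these genes is not shown. The microglial genes P2ry12, Tmem119, Cx3cr1, Csf1r and Siglech, chosen for mention after their values were seen, had between 3 and 9 merged peaks each and 0 listed peaks. Without Sall1 the odds ratio was 3.31 (adjusted p = 0.00821), and with any gene within 50000 bp of the peak 3.20 (adjusted p = 1.52e-04). With each gene counted once it was 4.97, with an unadjusted p of 0.00256 and an adjusted p of 0.123, which did not pass. MDM against YSM did not pass for this list (adjusted p = 0.887). Neuron, glia and vessel markers, genes of other cell types, were also over-represented among YSM-listed peaks (odds ratio 4.07, adjusted p = 0.0143). That result rested on Slc1a3, with 7 of the 9 peaks, and without it the odds ratio was 1.03.

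**Figure D1:**
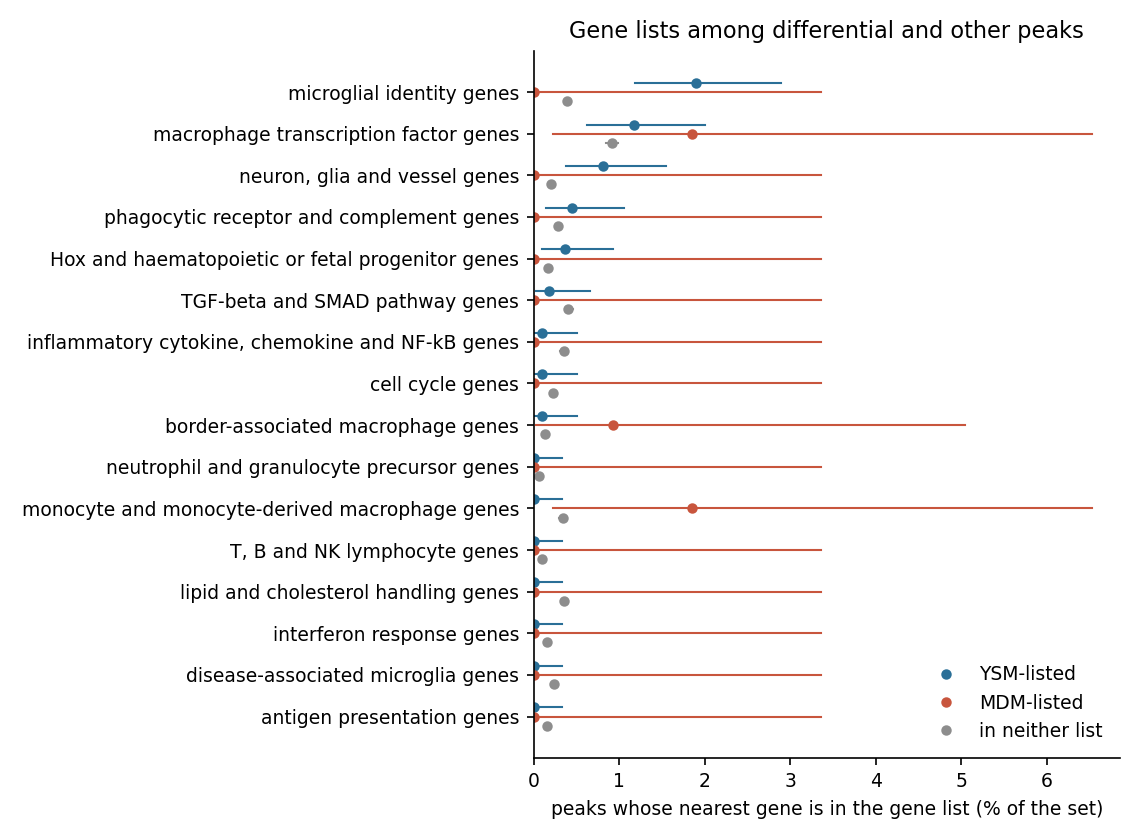
Share of peaks (%, x axis) whose nearest protein-coding gene belongs to each of 16 gene lists (y axis), for YSM-listed, MDM-listed and other merged peaks, with points for the share and lines for exact 95% intervals that cover counting error only. The microglial identity list took 1.90% of YSM-listed peaks and 0.393% of the peaks in neither list.

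Around Sall1, YSM-listed peaks were dense. The gene (NCBI gene 58198) lies on chromosome 8 from 89027242 to 89044162 in mm10 and is the 1 protein-coding gene between 88900000 and 89500000. In that region, chosen after seeing the data, 22 of 33 merged peaks (66.7%) were YSM-listed and 0 were MDM-listed. The YSM-listed peaks ran from 88914077 to 89396855, up to 352693 bp beyond the gene's higher coordinate, 89044162. Without strand, upstream and downstream of the gene were not told apart. Of the 12 merged peaks assigned to Sall1, 7 were YSM-listed (adjusted p = 2.54e-07, one-sided hypergeometric test over 11329 genes), with 4 of them inside the gene, at 89028268 to 89028570, 89042796 to 89043026, 89043320 to 89043637 and 89043704 to 89043904. All 33 merged peaks of the region, listed or not, had at most 3 subpeaks, so at least 1 library lacked a call at each. Sall3 (chromosome 18, 80966989 to 80987021) had its 5 YSM-listed peaks outside the gene, from 496 to 61372 bp away (adjusted p = 3.38e-04). Nav3 (chromosome 10, 109681260 to 110455722) had its 6 inside the gene (adjusted p = 1.55e-04). Adjusted over the list alone, the same number of microglial identity genes passed as over all genes, 3 and 3.

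**Figure D2:**
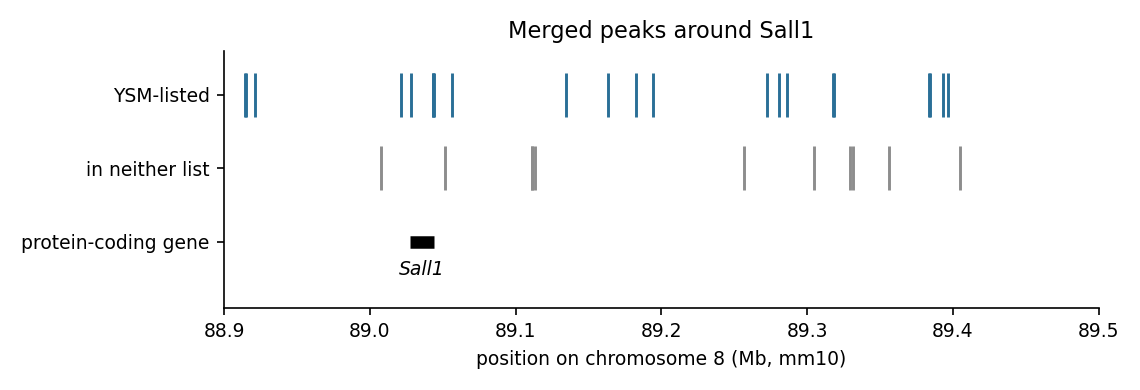
Merged peaks around Sall1 on chromosome 8 (x axis, position in Mb, mm10), with 1 vertical line per peak, YSM-listed peaks in the upper row, peaks in neither list in the middle row and the gene below. Of the 33 merged peaks in the region, 22 were YSM-listed.

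Outside the fixed lists, YSM-listed peaks were concentrated at single genes. Magi1, a scaffold protein of cell junctions, held 12 YSM-listed peaks among 26 merged peaks (adjusted p = 7.60e-12), of which 11 were inside the gene (chromosome 6, 93675453 to 94283929). Klf12, a Krüppel-like transcription factor, held 10 of 15 (adjusted p = 7.60e-12), and Ptprm, a receptor tyrosine phosphatase, 10 of 18 (adjusted p = 7.09e-11). Adamts16, a secreted metalloprotease, held 7 of 12, the RNA-editing deaminase gene Adarb1 6 of 10, Klhl3 6 of 15, the junctional adhesion molecule gene Jam2 5 of 7, the retinoid X receptor gene Rxrg 5 of 13 and Sdk1 5 of 24, all past the threshold (adjusted p from 3.88e-06 to 0.00761 except for Adamts16, at 2.54e-07). Not all of these peaks were inside their gene. Of the 7 Adamts16 peaks, 1 was inside and the farthest lay 93525 bp away, and Rxrg and Sdk1 had 2 inside each. Some listed peaks of a gene were close neighbours, as at Magi1 (94283620 to 94283971 and 94283972 to 94284172). At Jam2 they were 84774062 to 84774370, 84774427 to 84774627 and 84774793 to 84774993. The single-gene test counted each as independent and was not run with neighbours merged. Its counts can therefore exceed the number of separate sites, and its p-values can be too small. Among 11329 genes, 65 passed for the YSM list. None passed for the MDM list (0 genes, with 77 at an unadjusted p below 0.05), whose genes held at most 2 listed peaks each.

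The list of monocyte and monocyte-derived macrophage genes held 2 MDM-listed peaks, at Klf2 and Lyz1, and 0 YSM-listed peaks. The MDM share was 1.85%, against 0.342% of the peaks in neither list (odds ratio 5.50, 95% interval 1.35 to 22.4, Fisher's exact p = 0.0536, adjusted p = 0.465). Neither this difference nor that between the MDM and YSM lists (exact p = 0.00787, adjusted p = 0.126) passed the threshold. The peak at Klf2, a transcription factor of quiescent leukocytes and endothelium, spanned 72322513 to 72322735 on chromosome 8, with its centre 970 bp from the gene. The peak at Lyz1, a lysozyme gene, lay 9100 bp from it. Runx3, Ccr2, Ms4a7 and Lyz2, chosen for mention after their values were seen, had 25, 8, 8 and 4 merged peaks and 0 listed peaks.

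Macrophage transcription factor genes held 2 MDM-listed peaks, at Klf2 and Tfec, and 13 YSM-listed peaks, at Sall1 (7), Sall3 (5) and Mef2d (1), with adjusted p = 0.887 and 1 against the peaks in neither list. The Tfec peak, inside the gene at 16896613 to 16897273 on chromosome 6, combined 9 subpeaks. Adjusted over the list alone, 2 genes passed for the YSM list, Sall1 and Sall3, as over all genes. Of the other lists, border-associated macrophage genes had 1 MDM-listed peak at the chemokine gene Ccl24 and 1 YSM-listed peak at the lectin gene Cd209a. Phagocytosis and complement genes had 5 YSM-listed peaks, all at the scavenger receptor gene Marco (5 of 8 merged peaks, adjusted p = 4.75e-05), and the list as a whole did not pass (adjusted p = 0.887). The Marco peaks all lay outside the gene, 6928 to 31097 bp from it. Marco was the 1 gene of that list to pass, both adjusted over the list alone and over all genes. Hox and progenitor genes had 4 YSM-listed peaks, 2 at the homeobox gene Meis1 and 1 each at Gata2 and Hlf (adjusted p = 0.808). TGF-beta and SMAD genes had 2, at Bmpr1a and Smad1 (adjusted p = 1), inflammatory genes 1, at Cd14 (0.848), and cell cycle genes 1, at Cdkn2a (1). Antigen presentation, interferon response, disease-associated microglia, lipid and cholesterol, neutrophil and lymphocyte genes held 0 peaks in either list. For lipid and cholesterol genes the YSM test gave an exact p = 0.0369 and adjusted p = 0.443. Of the 48 tests, 2 passed.

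The other test that passed was of neuron, glia and vessel markers, genes of cell types other than the sorted macrophages. They took 9 YSM-listed peaks (0.815% against 0.201%, odds ratio 4.07, 95% interval 2.07 to 8.0, adjusted p = 0.0143) and 0 MDM-listed peaks. Of the 9 peaks, 7 were at Slc1a3, the astrocyte glutamate transporter gene (chromosome 15, 8634124 to 8710807, 26 merged peaks, adjusted p = 8.02e-05), and 1 each at the myelin genes Mog and Mbp. Slc1a3 was the 1 gene of the list to pass, adjusted over the list alone and over all genes. Without it the odds ratio was 1.03 (0.26 to 4.18, adjusted p = 1), with any gene within 50000 bp of the peak 2.19 (adjusted p = 0.338), and with genes counted once 3.52 (adjusted p = 0.641).

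The rule for named genes took Kcng2, Irs2, Ubl3, Sema6d, Armc2, Myof, Ifi47, Lrig1, Ttc39c, Klf2, Samd12 and Larp1b from the MDM list. From Myof on, each held 1 listed peak, a tie with the remaining genes, and was placed by distance alone. Irs2, the insulin receptor substrate gene, had its 2 listed peaks 7436 and 89762 bp away, and Sema6d, a semaphorin gene, had them 16880 and 73246 bp away. Both Armc2 peaks were inside the gene. The centre of the peak at Ifi47, an interferon-inducible GTPase gene, lay 112 bp from the gene, and that at Myof 49 bp. Both of these peaks overlapped their gene. The lists shared 2 genes, Fhit and Zc3h7a, where 3.52 would be shared by independent sets of 82 and 654 among 15255 genes with merged peaks.

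Most YSM-listed peaks were intervals that lacked a call in at least 1 library. Of the YSM-listed peaks, 71.6% (791) had at most 3 subpeaks, against 41.9% of the peaks in neither list (odds ratio 3.51, 95% interval 3.07 to 4.0, Fisher's exact p = 1.29e-87), and 46.7% (516) had exactly 2, against 11.1%. Of the MDM-listed peaks, 12% (13) had at most 3 (odds ratio 0.19, 0.11 to 0.34, exact p = 2.35e-11). Within deciles of peak width the odds ratios were 6.60 for the YSM list (exact p = 1.27e-170) and 0.36 for the MDM list (exact p = 7.85e-04). The lists differed from each other (odds ratio 0.054, 0.030 to 0.098, exact p = 1.05e-34). The number of subpeaks depends on the same accessibility that decided the lists, so it is not an independent property of the peaks. Width is tied to it, since the number of subpeaks sets the greatest width an interval had. MDM-listed peaks were wider, with a median of 280 bp against 235 bp for the peaks in neither list, a difference of 45 bp (two-sided permutation p = 1e-05, the smallest these permutations can give). The YSM median was 239 bp, a difference of 4 bp that did not pass (permutation p = 0.148), and on mean log2 width the YSM difference was 0.03 (permutation p = 0.0237).

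**Figure D3:**
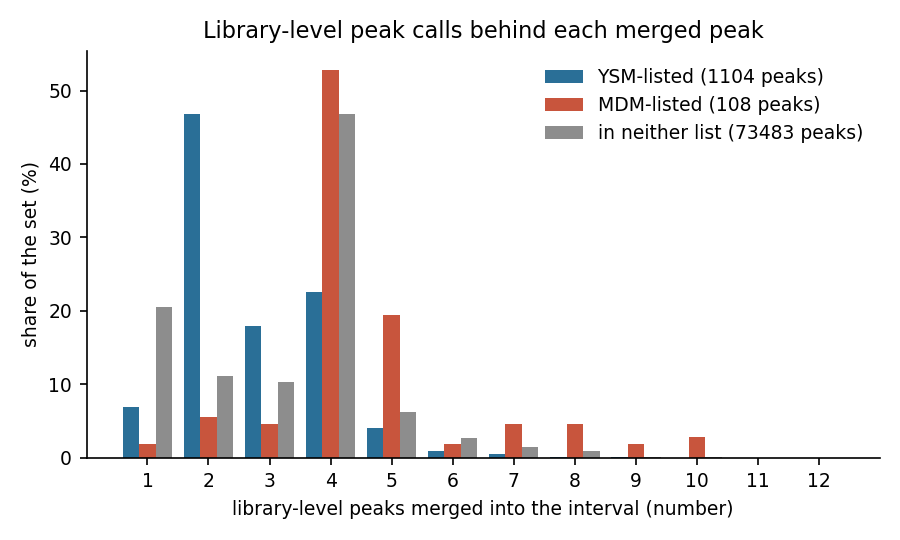
Share of each peak set (%, y axis) by the number of library-level peaks merged into the interval (x axis), as bars for YSM-listed, MDM-listed and other merged peaks. YSM-listed peaks most often had 2 (46.7%), and 88.0% of MDM-listed peaks had at least 4.

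YSM-listed peaks were uneven along the genome. Chromosome 14 held 7.35% of them against 3.66% of the peaks in neither list (odds ratio 2.09, 95% interval 1.66 to 2.63, adjusted p = 4.58e-07), and chromosome 8, which carries Sall1, 8.71% against 4.83% (1.88, 1.52 to 2.32, adjusted p = 1.33e-06). Chromosome 6, which carries Magi1, was also above the background (1.41, adjusted p = 0.0321). Chromosome X held 8 YSM-listed peaks (odds ratio 0.30, 0.15 to 0.60, adjusted p = 7.17e-04), and chromosomes 4 (0.57, adjusted p = 0.00191) and 19 (0.53, adjusted p = 0.0321) were below the background. No chromosome passed for the MDM list, which had 0 peaks on chromosome 17 (exact p = 0.0103, adjusted p = 0.0588) and 0 on chromosome X (adjusted p = 0.446). With YSM-listed peaks within 50000 bp of each other counted once, 3 of the 6 chromosomes passed and chromosomes 4, 6 and 19 did not. Among peaks farther than 1000 bp from gene ends, chromosome 19 did not pass (adjusted p = 0.0878).

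Listed peaks also clustered. Of the 1102 YSM-listed peaks on assembled chromosomes, 495 (44.9%) had another YSM-listed peak within 50000 bp, where random draws gave 138 ± 14.7 (SD, 10000 draws), a ratio of 3.58 (one-sided permutation p = 1e-04, the smallest these draws can give). The ratio was 10.02 within 10000 bp and 1.72 within 200000 bp. Of the MDM-listed peaks, 12 of 108 had a neighbour from their list, against 1.31 ± 1.60 (one-sided permutation p = 1e-04, also the smallest), a ratio of 9.13 that was 5.50 within 200000 bp. Within 10000 bp, 2 MDM-listed peaks did, a ratio of 6.81 that did not pass (one-sided permutation p = 0.135). Neighbouring peaks were not merged before these tests. With peaks of the same list within 1000 bp merged into 1, the YSM list held 1022 peaks in place of 1104. Pieces of 1 accessible region can thus have raised the short-range ratios.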

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

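The alternatives on subpeak number, on the nearest gene end, without the top gene of a list and on peaks far from gene ends were chosen after seeing the data. Of 439 values under an alternative, over 92 results, 406 kept their direction and side of the threshold or, for counts and ratios, stayed close to the first value, 12 lost the threshold, 1 gained it (YSM width on the log2 scale) and 5 counts or ratios moved. Another 15 comparisons changed direction, and none of them passed the threshold before or after. Direction was read from the odds ratio or, where a set held 0 peaks, from the shares, since an odds ratio with a constant added to an empty cell can lie above 1 for a share of 0. Their odds ratios under the alternative follow. With any gene within 50000 bp these were, for MDM against neither, each with 0 peaks at first and 1 then, disease-associated (2.02), lipid (1.77), phagocytosis (1.77) and neutrophil genes (4.69), for YSM against neither TGF-beta genes (1.54), and for MDM against YSM phagocytosis genes (1.28). With genes counted once the YSM ones were border-associated (1.17), TGF-beta (1.65) and phagocytosis genes (0.77). Phagocytosis genes also turned for YSM within 10000 bp (0.72) and without Marco (0.16, with 0 peaks left), and by the nearest gene end, again from 0 peaks to 1, for MDM against neither (3.29) and against YSM (2.05). Macrophage transcription factor genes turned for YSM without Sall1 (0.60), and chromosome 12 with neighbouring peaks counted once (1.1). The ratio of the YSM to the MDM list ranged from 9.55 to 10.1 with neighbouring peaks merged, autosomes alone or at least 2 subpeaks, and was 3.29 with at least 4 subpeaks. Of 6 chromosomes, 3 passed with neighbouring peaks counted once. Of 2 gene list tests, 1 passed with any gene within 50000 bp, and 1 passed without the gene with most YSM-listed peaks. With genes counted once, 0 passed, while the YSM odds ratio for microglial identity was 4.97 against 4.91 at first. Counting genes once leaves fewer units and also stops several peaks of 1 gene from counting as independent. Which of these cost the threshold was not tested. The YSM adjusted p ranged over the alternatives from 4.00e-07 to 0.123 for microglial identity and from 0.00767 to 1 for neuron, glia and vessel markers. The cause of the other changes was not tested either. Not run were a stricter threshold (the lists carry no score that could be read), the promoter on both sides, and the alternatives on base composition and motifs. No paired analysis was possible because the lists carry no value per library, and for the same reason no library was left out in turn. With the depth of each library not analysed here, a peak outside both lists is not shown to be equally open in the groups.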

Other observations

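The tests on the length of the lists and on neuron, glia and vessel markers were chosen after the result was seen. The tests on chromosomes, on shared loci and on gene families were set before their results were seen. All genes named in this paragraph and the next were chosen after their values were seen, unless the text has named them already. They are single genes, and no group of them was tested. The retinoic acid receptor gene Rarb held 5 YSM-listed peaks among 7 merged peaks (adjusted p = 2.03e-05). Among the 65 genes that passed were also Prox1 and Elavl4 (4 of 5 each, adjusted p = 1.77e-04), Runx1t1 (3 of 3, 0.00140), Dlgap2 (4 of 13, 0.00870), Csmd3 (3 of 5, 0.00870), Nr2f1 and Srrm4 (3 of 8 each, 0.0372) and Cxcl13, a B cell chemoattractant gene (3 of 7, 0.0244). These are one-sided hypergeometric tests over 11329 genes, with neighbouring peaks counted separately.

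In the MDM list, 1 peak each lay nearest to immune genes outside the fixed lists. The peak assigned to the chemokine receptor gene Cxcr4 (chromosome 1, 128570261 to 128570771) lay 17683 bp from it. Peaks assigned to Retnla, Gpr65 and Slfn3 lay 11155, 43390 and 9161 bp away, and those of Traf6 and Nlrc3 lay inside the gene. A further peak lay 2486 bp from Apoc4, in the apolipoprotein gene cluster of chromosome 7 (19683839 to 19684054). No MDM-listed gene passed the single-gene test, which a gene with 1 MDM-listed peak could not pass.

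Of 553 gene families defined by a shared symbol stem, each with at least 20 merged peaks and 3 genes, 7 passed adjustment among YSM-listed peaks, all above the background. Each of the 7 held at least 1 gene that passed on its own, so a concentration in families cannot be told apart from one at single genes. The Sall family had 12 YSM-listed peaks at 2 of 3 genes (odds ratio 44.9, 95% interval 21.6 to 93.3) and the Adamts family 11 at 3 of 11 genes (24.6, 12.3 to 49.3). The Klhl family had 9 at 3 of 27 genes, 6 of them at Klhl3, and the olfactory receptor genes 8 at 5 of 68. The Magi, Klf and Ablim families each rested on 1 gene. As for shared loci, 3 MDM-listed peaks lay within 50000 bp of a YSM-listed peak, against 6.54 ± 2.49 (SD) in random draws (one-sided permutation p = 0.961 for more). No excess was thus seen, but the draws were matched on chromosome only. Peaks without an assigned gene made up 19.4% of the MDM list and 4.58% of the peaks in neither list. A tendency of the lists to share loci can therefore not be decided from these draws.

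The YSM list was 10.2 times as long as the MDM list. Of the YSM-listed peaks, 28.4% (95% interval 25.7 to 31.1) had at least 4 subpeaks, against 58.1% of the peaks in neither list, and among listed peaks with at least 4 the ratio was 3.29 (2.61 to 4.19). Neither value decides between explanations. A peak higher in YSM for any reason can be called in the YSM libraries and missed in the others. Of the 1104 YSM-listed peaks, 516 had exactly 2 subpeaks. The MDM-listed peaks did not mirror this, with 5.56% at exactly 2 subpeaks and 88.0% at 4 or more. What made the lists differ in this was not tested. A scale factor that raised every YSM peak, weak peaks missed in the MDM libraries through lower depth or signal-to-noise, and a difference in chromatin between the groups therefore cannot be told apart without values per library.

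Neuron, glia and vessel markers were over-represented among YSM-listed peaks, with 7 of the 9 peaks at Slc1a3. DNA of neural or vessel cells in the YSM libraries is a candidate explanation, although the cells had been sorted as macrophages. Without Slc1a3 the odds ratio was 1.03, but its interval (0.255 to 4.18) reaches the value with it, so such DNA and accessibility of Slc1a3 in the macrophages themselves cannot be told apart with so few peaks. Of the 22 list genes with merged peaks, 3 had a YSM-listed peak, and Snap25, Gfap, Aqp4, Slc1a2, Olig2, Cldn5 and Pecam1 had between 1 and 10 merged peaks each and 0 listed peaks, while outside the list Elavl4 (4 of 5 merged peaks), Dlgap2 (4 of 13), Csmd3 (3 of 5) and Srrm4 (3 of 8), genes best known from neurons, passed the single-gene test for YSM. These genes were picked after their values were seen, how far macrophages use them was not analysed here, and whether such DNA bears on the microglial identity genes was not tested and stays open.

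Chromosomes 8 and 14 held more YSM-listed peaks than the background. With YSM-listed peaks within 50000 bp counted once, the odds ratios were 1.64 (95% interval 1.25 to 2.13) and 1.92 (1.45 to 2.54). Runs of that spacing are thus argued against as the whole cause. Looser runs stay open, since the 22 peaks around Sall1 had wider gaps, as from 88921256 to 89021297, and still counted more than once. The background peaks were not thinned in this way. A shortage of gene ends on these chromosomes is argued against by odds ratios of 2.03 (1.63 to 2.54) and 1.81 (1.41 to 2.34) among peaks farther than 1000 bp from gene ends. An unequal copy number of these chromosomes between the cells of the groups might also give this and was not tested, and a difference between the groups in chromatin stays open and untested.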
